A study of Mus musculus with 2 samples.

How the data were processed

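The study measured messenger RNA in single cells of the mouse mammary gland at gestation day 18.5. Per the labels, cells that were CD45-negative, CD31-negative and EPCAM-positive were sorted from 14 samples, each stained with its own hashtag antibody, then pooled, and 45000 cells were loaded on 1 droplet lane (10x 5′ chemistry). By their titles the 2 GEO samples are the gene expression library and the hashtag library of that lane, though their descriptions name lane 2 and lane 3, which stays unresolved. The replicates are therefore the hashtagged samples, not the GEO samples. The deposited hashtag table names 4 samples Raggc (Rag2 and common gamma chain deficient mice without transfer), 5 samples Raggc IELp (the same genotype, with thymic intraepithelial lymphocyte precursors transferred at gestation day 10.5, 8 days before collection) and 5 samples WT (wild type). The genotype field of both GEO samples reads WT, which differs from the protocol text; groups were taken from the hashtag names alone. The labels do not state that each hashtag is a separate mouse. The p-values of the gene and share comparisons below therefore measure the spread between hashtagged samples. Those of the list test camera with its preset correlation set a list's genes against all other genes. The test of gene positions uses random gene sets. Neither of these measures the spread between samples.

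The deposited matrix holds raw UMI counts (unique molecules per gene or hashtag and cell barcode), whole numbers from 1 upward, for 32285 genes and 14 hashtags in 11230 barcodes. Per the submitters' processing notes, the authors used Cell Ranger (no version given) on the mm10 build and Seurat 4.4.0, with no further detail of either step. The matrix holds 63634667 gene UMIs, and its lowest barcode total was 500 UMIs. No filter on cell quality beyond barcode calling is stated.

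Cells were assigned to samples with Seurat 5.3.0 HTODemux on centred log-ratio hashtag counts (positive quantile 0.99, fixed seed). Cells needed at least 500 genes and at most 10% mitochondrial UMIs, which 6485 barcodes met; 4280 failed the gene minimum and 465 more failed the mitochondrial limit. Among the 6485 barcodes, 3149 (48.6%) held more than 1 hashtag, 749 (11.6%) held none, and 2587 (39.9%) were singlets. Only singlets entered the comparisons. The median count of a sample's own hashtag was 5.68 to 17.0 times that of the same hashtag in other cells. For Raggc 1 and Raggc 2 the hashtag background was highest, with medians of 30.0 and 86.0 UMIs in other cells.

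Clusters were made with scanpy 1.11.5 from all 6485 cells (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.5 with igraph 0.11.9). The milk protein, interferon and MHC, proliferation, immediate early, mitochondrial and ribosomal gene lists took no part in the clustering. The 18 clusters were named from marker lists: 3 were basal (myoepithelial), 5 alveolar, 1 luminal progenitor, 1 hormone-sensing, 1 mixed, and 7 not epithelial. The singlets comprised 2095 epithelial cells, 445 other cells and 47 cells of the mixed cluster.

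Counts were summed per sample over all epithelial cells, and separately over basal and alveolar cells, for samples with at least 20 cells of the class. This left 4 Raggc, 5 Raggc IELp and 5 WT samples for alveolar cells, and 2, 4 and 5 for basal cells. No sample held 20 progenitor or hormone-sensing cells, so those classes were not fitted. The sums were tested with edgeR 4.0.16 (TMM normalization, filterByExpr, quasi-likelihood fit with all groups together) at a Benjamini-Hochberg adjusted p of 0.05 over all genes tested. Below, "rose", "fell" and "passed" refer to that test. Levels are given as CPM (counts of a gene scaled to a common total of the summed counts), mean ± SD over samples, and fold changes as fitted log2 values with their standard error (SE). No batch was modelled, since the protocol text names 1 lane for all samples.

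A set of 27 gene lists was tested with camera and fry from limma 3.58.1, with adjustment over lists. Camera was run with a preset correlation of 0.01 between genes and again with an estimated correlation; fry asks whether a list's genes move 1 way on balance. Among all list calls in alveolar and basal cells, the estimated correlation kept 1, the interferon gamma and MHC class I list in alveolar cells of WT against Raggc IELp. A further 9 lists of markers of other cell types were summed per sample. Shares of the 4 epithelial classes were compared with exact two-sided permutation tests over all arrangements of the samples, adjusted over 12 tests; the smallest possible p was 0.00794. The comparisons of Raggc IELp and of WT with Raggc share the Raggc samples, so their overlap was set against 40 simulations of unchanged groups and 6 splits of those samples.

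Genes named below follow a rule set before the data were examined. Per class and comparison it takes the 8 genes with the smallest p in each direction among those past adjusted p 0.05 with a mean of at least 10 CPM, and up to 4 passing members of each list. Where no member passed, it takes up to 2 members with the smallest p, given as values. It always includes 14 genes (Csn2, Csn1s1, Wap, Lalba, Elf5, Stat5a, Prlr, Pgr, Krt5, Krt8, Rag2, Il2rg, Mki67, B2m) where measured; the text gives those that bear on each comparison. Among the genes taken by the rule, 1 is not reported here. Positions are from the GRCm38 annotation.

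The pipeline was tested on simulated data with known changes at this depth and number of samples. In alveolar cells the test recovered 28.4%, 71.6% and 97.0% of genes changed 1.5-, 2- and 4-fold for transfer, 29.9%, 70.2% and 98.5% for WT against Raggc, and 43.3%, 76.1% and 95.5% for WT against Raggc IELp. In basal cells it recovered 7.46%, 28.4% and 80.3% for transfer, 11.9%, 14.9% and 69.7% for WT against Raggc, and 25.4%, 61.2% and 89.4% for WT against Raggc IELp. Over all epithelial cells it recovered 19.4%, 53.7% and 93.9% for transfer.

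The alternatives tried were DESeq2 1.42.0 with its size factors, upper-quartile normalization, leaving out milk protein genes, no low-count filter, leaving out each sample, a replicate block and only the groups compared. For cells they were another hashtag rule, mitochondrial limits of 5% and 20%, Scrublet doublet removal, Leiden resolution 1.0, clustering with the left-out lists kept, and other cell minimums. Further alternatives were added after the data were seen: a strict hashtag rule (top hashtag at least 4 times the second), cells thinned to 2000 UMIs for the gene comparisons, the largest alveolar cluster alone, alveolar cells without clusters of few genes, at least 10 cells in basal sums, and Raggc 1 and Raggc 2 left out. R 4.3.3 and Python 3.11.15 were used.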

Results

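Messenger RNA was counted in single sorted mammary epithelial cells of mice in late pregnancy. The 14 hashtagged samples fell into 3 groups by their names. Of these, 4 came from mice deficient in Rag2 and the common gamma chain, a genotype meant to lack lymphocytes (Raggc). Another 5 came from such mice given thymic intraepithelial lymphocyte precursors 8 days earlier (Raggc IELp), and 5 were wild type (WT). Samples held 97 to 297 assigned cells, with a median of 4996 to 7401 gene UMIs per cell. Total gene UMIs were 2254908, 1034443, 689343 and 1346519 in Raggc 1 to 4. They were 994661, 1141731, 858633, 2057202 and 1041602 in Raggc IELp 1 to 5, and 1917131, 1500912, 2249447, 2137232 and 1557992 in WT 1 to 5. The 445 assigned cells that were not epithelial made up 36.8% ± 20.4 (SD, n = 4) of assigned cells in Raggc, 17.5% ± 7.09 (n = 5) in Raggc IELp and 8.15% ± 2.15 (n = 5) in WT.

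The genes disrupted in the deficient mice gave too few UMIs to check the genotypes. Rag2 (chromosome 2, 101624712 to 101632528), which encodes part of the antigen receptor recombinase, gave 3, 2, 0 and 1 UMIs in Raggc 1 to 4. It gave 1, 1, 0, 1 and 1 UMIs in Raggc IELp 1 to 5 and 0, 0, 1, 1 and 0 in WT 1 to 5. A UMI of Rag2 was seen in 0.963% of 623 Raggc cells, 0.571% of 700 Raggc IELp cells and 0.158% of 1264 WT cells. A count of 0 would have allowed up to 0.482%, 0.429% and 0.237% of cells with a UMI. Il2rg (chromosome X, 101264385 to 101268255), which encodes the common gamma chain, gave 9, 7, 1 and 3 UMIs in Raggc 1 to 4, 1, 0, 1, 0 and 6 in Raggc IELp 1 to 5, and 2, 0, 1, 15 and 7 in WT 1 to 5. A UMI of Il2rg was seen in 2.73% of Raggc, 1.00% of Raggc IELp and 1.42% of WT cells. Epithelial cells, which should lack Il2rg, held 3, 2 and 3 of the UMIs of the 3 groups. Cd3e, a T cell receptor component, had 0 UMIs in both deficient groups and 9 UMIs in 2 WT cells (0.158% of WT cells). A count of 0 allows up to 0.482% of Raggc and 0.429% of Raggc IELp cells with a UMI. The sort was also meant to keep CD45-negative cells only, though macrophages and mast cells were among the assigned cells. With so few UMIs these counts do not tell the groups apart.

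Shares of epithelial cell classes were compared to see whether the make-up of the sorted epithelium differed between the groups. Among the sorted epithelial cells, WT samples had a larger share of basal (myoepithelial, contractile) cells than Raggc samples, and a smaller share of alveolar (milk-producing) and luminal progenitor cells. Basal cells were 49.8% ± 9.60 (SD, n = 5) of epithelial cells in WT, 31.2% ± 12.6 (n = 5) in Raggc IELp and 19.8% ± 4.63 (n = 4) in Raggc. Alveolar cells were 42.9% ± 8.18, 60.6% ± 11.4 and 69.0% ± 4.81 in the same order. Luminal progenitors were 5.29% ± 2.20, 6.40% ± 2.31 and 10.5% ± 1.93, and hormone-sensing cells 2.07% ± 1.13, 1.78% ± 1.33 and 0.737% ± 0.980. Each of the differences between WT and Raggc in basal, alveolar (-26.2 percentage points) and progenitor cells (-5.17) had an exact two-sided permutation p of 0.00794, the smallest possible, and an adjusted p of 0.0318 over 12 tests. All 5 WT samples lay above every Raggc sample in basal share. With transfer, the basal share differed by 11.4 points (exact adjusted p = 0.179), the alveolar share by -8.39 (exact adjusted p = 0.276) and the progenitor share by -4.06 (exact adjusted p = 0.0762), none past the threshold. Between WT and Raggc IELp the basal share differed by 18.6 points (exact adjusted p = 0.0952) and the alveolar share by -17.8 (exact adjusted p = 0.0762). Hashtag doublets made up 57.8% of basal and 33.8% of alveolar cells, and were left out of these shares. The WT and Raggc difference lost its call under the strict hashtag rule (23.4 points for basal cells) and without any single sample, where fewer arrangements can be drawn. The progenitor call was also lost at resolution 1.0, with the left-out lists kept in clustering, with the 20% mitochondrial limit, with Scrublet calls removed and on the logit scale.

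**Figure D1:**
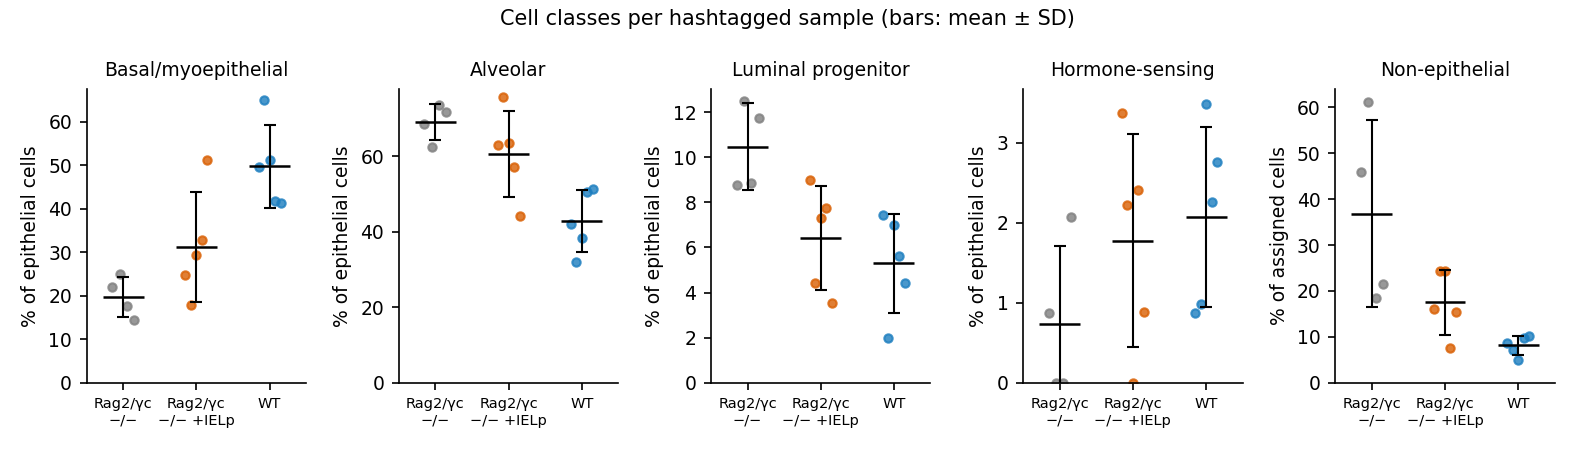
Share of each epithelial class (percent of epithelial cells, vertical axis) in the 14 samples, by group, with the mean and SD. Basal shares ran from 14.5% to 25.0% in Raggc, 17.8% to 51.3% in Raggc IELp and 41.4% to 65.0% in WT.

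Alveolar cells of Raggc IELp and Raggc samples were compared to ask how transferred precursors bear on late-pregnancy milk-producing cells. With transfer 9 of 10 milk protein genes and 10 of 11 milk fat globule genes rose, and 1 of 24 proliferation genes fell. Wap (ENSMUSG00000000381; chromosome 11, 6635483 to 6638654), a whey protein gene, was at 10860 ± 2566 CPM (SD, n = 5) with transfer and 2574 ± 682 CPM (n = 4) without, a log2 change of 2.07 (SE 0.256). Csn2 (ENSMUSG00000063157; chromosome 5, 87692619 to 87699429), beta-casein, was at 150100 ± 16180 and 84750 ± 7700 CPM, a log2 change of 0.83 (SE 0.0933). In total 107 genes rose and 22 fell among 7387 tested. All of the named genes said to rise or fall passed at an adjusted p of 0.05.

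Of the 10 milk protein genes tested, 9 rose (10 adjusted over the list alone), with a median log2 change of 1.05. The caseins Csn1s1 and Csn3 rose by 0.76 and 0.95. In camera the list had an adjusted p of 7.45e-15, with adjusted p = 0.0757 with an estimated correlation, and fry gave 0.00286. In basal cells, which do not make milk, Csn2 was at 12450 ± 9087 CPM (n = 4) with transfer and 5520 ± 2521 (n = 2) without. Among the 11 tested genes of milk fat globule secretion, 10 rose (11 adjusted over the list alone), with a median of 0.83 and adjusted p = 0.0739 with an estimated correlation. They included Fabp3, a fatty acid carrier, at 1.31, Plin2, a lipid droplet coat protein, at 0.83, Muc1, a surface mucin, at 1.26, and the transporter Abcg2 at 1.17. Lao1, an amino acid oxidase secreted in milk, had the smallest p and rose by 2.09 (SE 0.227). Among secretory immunity genes 3 of 8 rose (5 adjusted over the list alone; adjusted p = 0.0739 with an estimated correlation). These were Ltf, the iron-binding lactoferrin, at 1.69, Lcn2, which binds bacterial siderophores, at 0.74, and Wfdc18 at 0.66.

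Among 19 genes of fatty acid and triglyceride synthesis, 3 rose (5 rose and 2 fell adjusted over the list alone; adjusted p = 0.658 with an estimated correlation). They were Olah, which ends chain growth at medium length, at 1.12, Me1, malic enzyme, at 0.80, and Acaca, acetyl-CoA carboxylase, at 0.62. Acadl, a fatty acid oxidation enzyme, rose by 1.09. B4galt1, a part of lactose synthase, rose by 0.73 as 1 of 12 lactose and glucose genes, and the secretory stress regulator Xbp1 by 0.69 as 1 of 18 unfolded protein response genes. Among 5 luminal progenitor genes 2 rose (3 adjusted over the list alone; adjusted p = 0.0757 with an estimated correlation), Cd14, a co-receptor for bacterial lipopolysaccharide, at 1.02 and Sox9 at 0.40. Cox4i1, a respiratory chain subunit, rose by 0.33 and Bst2, an interferon-induced antiviral gene, by 0.42.

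All 24 proliferation genes tested had log2 values below 0, with a median of -0.87, and 1 fell (9 adjusted over the list alone; adjusted p = 0.1995 with an estimated correlation). That gene was Rrm2, a subunit of ribonucleotide reductase, at -1.97. Mki67, another member of the list, had a value of -0.76 (adjusted p = 0.248). Outside the list, the chromatin remodeler Hells fell by 1.80 on the log2 scale and the chromatin protein Hmgb2 by 1.18. Of 13 mitochondrially encoded genes 3 fell (8 adjusted over the list alone; adjusted p = 0.564 with an estimated correlation): mt-Nd1 at -0.36, mt-Nd5 at -0.36 and mt-Nd2 at -0.35. Further genes that fell were Gm26917 at -1.48, Camk1d at -0.86, Sptbn1 at -0.73 and Prmt1 at -0.57. For 86 ribosomal protein genes 0 passed in edgeR, the median was 0.07 and adjusted p = 0.777 with an estimated correlation. Values that did not pass were Lalba, alpha-lactalbumin, at 1.25 (adjusted p = 0.146), Elf5, a regulator of alveolar fate, at 0.14, Stat5a at 0.16, Prlr at -0.05 and B2m at -0.05.

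Myeloid marker genes summed to 53.1 ± 31.4 CPM in alveolar cells of Raggc and 33.3 ± 6.63 in those of Raggc IELp, endothelial markers to 9.50 ± 2.17 and 4.46 ± 1.89, pericyte markers to 23.3 ± 7.47 and 12.4 ± 2.53, adipocyte markers to 69.3 ± 14.3 and 49.6 ± 19.8, and erythroid markers to 2.82 ± 0.955 and 159.8 ± 335 CPM, the last from Raggc IELp 5 (759 CPM; others 0 to 34.9). In the largest alveolar cluster alone, an alternative chosen after the data were seen, the count fell from 129 genes to 34: Csn2 (log2 0.19), Wap (0.86), Fabp3 (0.56) and Csn1s1 (0.04) no longer passed, Lao1 (1.41), Ltf (1.94) and Muc1 (1.17) did, and Gm26917 turned to 0.73. It was 59 without Raggc 1 and Raggc 2, 56 under the strict hashtag rule and 32 in cells thinned to 2000 UMIs, where 1768 genes were tested in place of 7387.

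**Figure D2:**
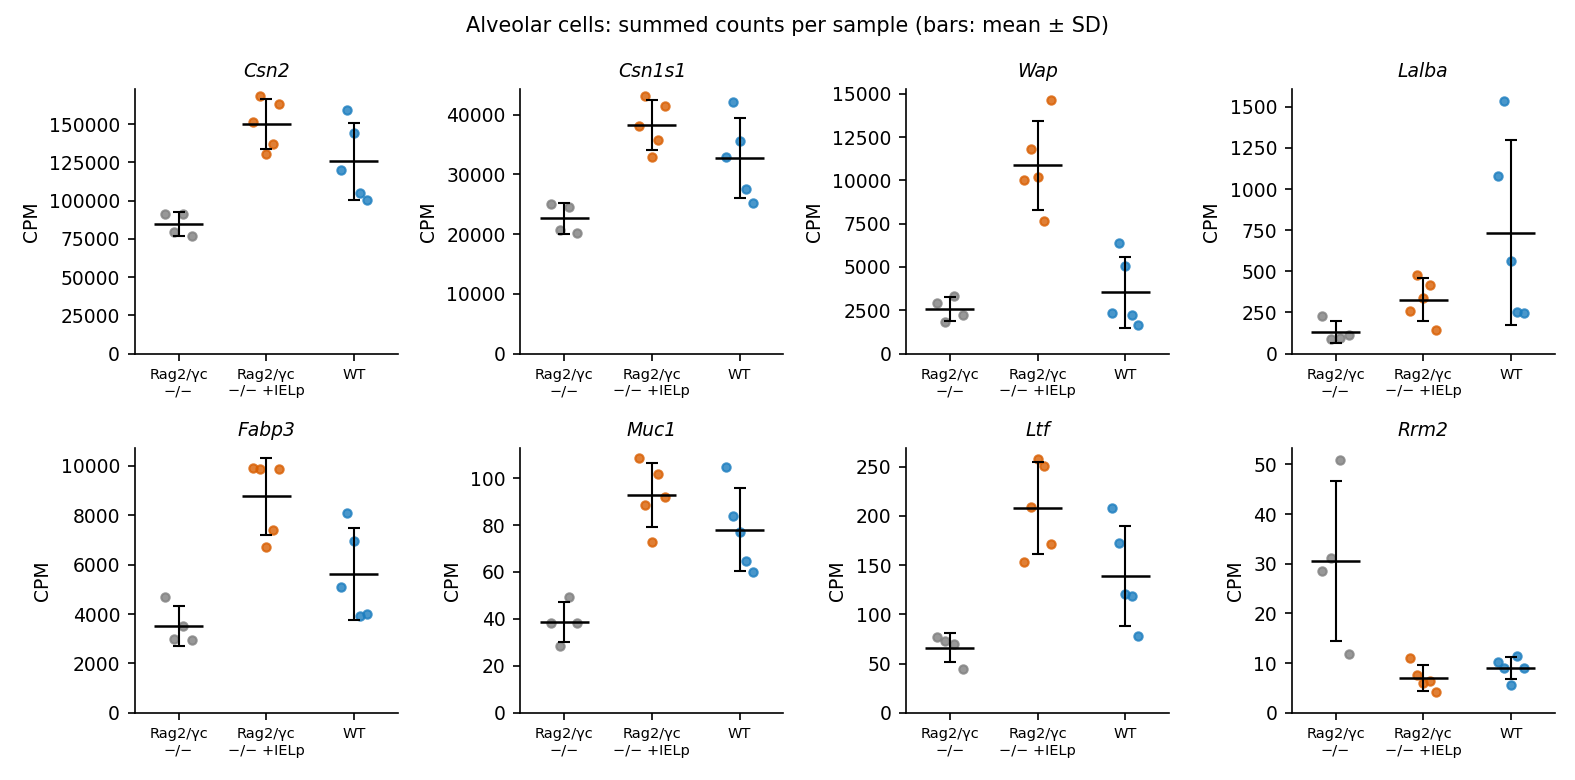
CPM of 8 genes in alveolar cells of each sample (points), by group, with the mean and SD. Wap was at 2574 CPM in Raggc, 10860 in Raggc IELp and 3541 in WT, while Rrm2 was at 30.6, 7.02 and 9.07.

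**Figure D3:**
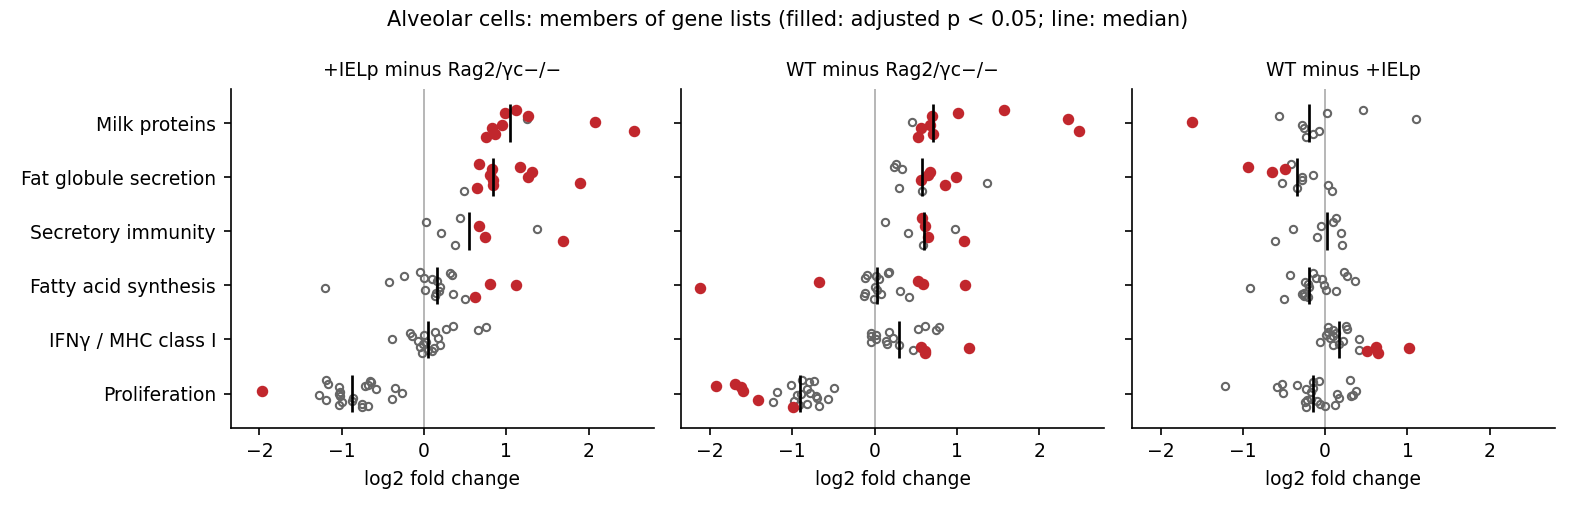
Fitted log2 fold changes of the members of 6 gene lists in alveolar cells (points), for the 3 comparisons. With transfer all 24 proliferation genes lay below 0 and all 11 fat globule genes above it.

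Over all epithelial cells the transfer comparison also takes in the class shares, and 13 genes rose and 0 fell in edgeR among 9282 tested, with 1227 at an unadjusted p under 0.05. They included Wap at 1.86, Lao1 at 1.87, Fabp3 at 1.13, Acadl at 0.87, Lcn2 at 0.60 and Sftpd, the lung surfactant lectin, at 1.77. Socs3, a feedback inhibitor of cytokine signalling, rose by 1.201, Ifi47, an interferon-induced GTPase, by 1.298, Ucp2 by 0.61 and Ndfip1 by 0.66. Socs3 passed in neither class, with 0.94 in alveolar cells (edgeR adjusted p = 0.121) and 0.30 in basal cells (0.693). With and without transfer it was at 29.1 and 14.2 CPM in alveolar cells, and at 836 and 676 in basal cells. Its rise over all cells cannot be told apart from the basal share, 31.2% with transfer and 19.8% without. Camera called 9 lists and 0 with an estimated correlation. In edgeR 0 genes passed without Raggc 1 and Raggc 2 (1060 at an unadjusted p under 0.05), and 1 did under the strict hashtag rule. DESeq2 called 119 genes, and 243 passed in edgeR without Raggc IELp 2.

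In basal cells (n = 4 with transfer, 2 without) 1 gene rose and 1 fell with transfer among 6713 tested, with 481 at an unadjusted p under 0.05. Igfbp5 (chromosome 1, 72858065 to 72874865), a binding protein of insulin-like growth factors, fell from 1287 ± 342 to 439 ± 39.5 CPM, by 1.54 on the log2 scale. Selenom, a selenoprotein of the endoplasmic reticulum, rose by 0.96 (SE 0.178), a call lost under the ratio hashtag rule (Selenom 0.52), with the replicate block, with only the groups compared, in thinned cells, and without Raggc 4, Raggc IELp 4 or Raggc IELp 5. All 13 contractile genes had values above 0 and 0 passed in edgeR (6 adjusted over the list alone; adjusted p = 0.787 with an estimated correlation), among them Tpm2 at 0.52 and Tagln at 0.40. The 8 milk protein genes tested had a median of 0.96, and 0 passed (5 adjusted over the list alone). Myeloid markers summed to 133 ± 52.3 CPM in basal cells of Raggc and 78.9 ± 22.2 in those of Raggc IELp, endothelial markers to 14.1 ± 2.75 and 5.05 ± 4.43, and T and NK cell markers to 14.1 ± 2.75 and 5.93 ± 4.04, the last 2 from very few UMIs per sample. In simulated data 28.4% of genes changed 2-fold were recovered for this comparison.

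The WT and Raggc alveolar cells were compared to ask how the genotype, without transfer, bears on these cells. In WT alveolar cells 9 of 10 milk protein, 4 of 8 secretory immunity and 4 of 19 interferon gamma and MHC class I genes were higher than in Raggc cells, and 6 of 24 proliferation genes were lower. Among 7387 genes tested 171 were higher and 80 lower in WT (n = 5 and 4). Lalba, which with B4galt1 makes lactose, was at 734 ± 562 CPM in WT and 131 ± 66.2 in Raggc (log2 2.36, SE 0.402). B2m (chromosome 2, 122147687 to 122153082), the light chain of MHC class I, was at 808 ± 67.4 and 547 ± 15.2 CPM (log2 0.56, SE 0.0970).

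Of 10 milk protein genes 9 were higher in WT (9 adjusted over the list alone; adjusted p = 0.197 with an estimated correlation). Csn2 was higher by 0.57, Csn1s2a by 0.71, the iron carrier Trf by 1.01 and the lipase Cel by 1.57, while Wap had a value of 0.45 (adjusted p = 0.360). In fat globule secretion 5 of 11 were higher (8 adjusted over the list alone; adjusted p = 0.203 with an estimated correlation), among them Plin2 at 0.86, Muc1 at 0.98 and the fatty acid receptor Cd36 at 0.65. In secretory immunity 4 of 8 were higher (5 adjusted over the list alone; adjusted p = 0.110 with an estimated correlation), with Ltf at 1.08, Lcn2 at 0.64, Wfdc18 at 0.61 and Lbp at 0.57. Among 19 interferon gamma and MHC class I genes 4 were higher (6 adjusted over the list alone; adjusted p = 0.0694 with an estimated correlation; fry 0.000767). These were the MHC class I genes H2-K1 at 0.61, H2-D1 at 0.61 and H2-Q7 at 1.15, and B2m. Of 6 type I interferon genes 0 passed in edgeR, with Isg15 at -0.80 (adjusted p = 0.277).

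Of 24 proliferation genes 6 were lower in WT (18 adjusted over the list alone; adjusted p = 0.145 with an estimated correlation), with Rrm2 at -1.60, the replication helicase subunits Mcm3 at -1.93 and Mcm2 at -1.63, and the cyclin Ccna2 at -1.41. Mki67, a marker of cycling cells, was lower at -0.99. In the unfolded protein response list 5 were lower and 1 higher of 18 (8 lower adjusted over the list alone; adjusted p = 0.275 with an estimated correlation), with the chaperones Hsp90b1 at -0.55, Hspa5 at -0.57 and Calr at -0.51, and Manf at -0.67. Among 15 cholesterol synthesis genes 2 were lower (9 adjusted over the list alone; adjusted p = 0.171 with an estimated correlation), among them Msmo1 at -1.42. In fatty acid and triglyceride synthesis 3 were higher and 2 lower of 19, with Olah at 1.10, the desaturase Scd2 at -2.12 and the lipid synthesis regulator Srebf1 at -0.67. Other genes with the smallest p were Gm43305 at 3.60, Cep85, a centrosome protein, at 2.12, Ifi47 at 2.44, the mitochondrial carrier Ucp2 at 1.201, Acadl at 1.17, Cd14 at 1.45, Def8 at -3.07, the complement inhibitor Cd59a at -1.33, Ciapin1 at -1.01, Npm3 at -0.69, Dynll1 at -0.70 and the chaperonin Hspd1 at -0.62. In WT alveolar cells myeloid markers summed to 26.2 ± 8.11 CPM, adipocyte markers to 48.4 ± 11.5, endothelial markers to 7.60 ± 1.75 and pericyte markers to 19.04 ± 3.67, beside the Raggc values above. In cells thinned to 2000 UMIs 28 of 1768 genes passed, and B2m (0.44), H2-K1 (0.38), H2-D1 (0.34) and Csn2 (0.42) did not. The count was 79 under the strict hashtag rule and 103 without Raggc 1 and Raggc 2.

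In basal cells of WT (n = 5) against Raggc (n = 2) 0 genes were higher and 5 lower in edgeR among 6713 tested, with 459 at an unadjusted p under 0.05. Def8 (chromosome 8, 123442956 to 123467076), a regulator of lysosome positioning, was at 57.0 ± 26.2 CPM in WT and 1564 ± 101 in Raggc, a log2 change of -4.77. The others were Sparc, a matrix glycoprotein, at -0.51, Btg2, an antiproliferative gene, at -0.98, Cd59a at -1.68 and Gm21190 at -2.69. No list passed in camera. B2m and H2-K1 had values of -0.50 (adjusted p = 0.329) and -0.54 (adjusted p = 0.371). In the test of the difference between classes, the WT minus Raggc effect was lower in basal than alveolar cells for B2m by -0.98 (adjusted p = 0.00458) and for H2-K1 by -1.01 (adjusted p = 0.00452). Myeloid markers summed to 77.3 ± 8.01 CPM in these WT cells and fibroblast markers to 1136 ± 141, against 133 ± 52.3 and 834 ± 354 in Raggc. Only Def8 of the 5 still passed with upper-quartile normalization, with the replicate block, in thinned cells (3098 genes tested), and without Raggc 1, Raggc 4 or WT 3, while at least 10 cells per sample gave 15 genes.

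The WT and Raggc IELp samples were compared to ask where cells differed from wild type after transfer. In alveolar cells (n = 5 and 5) 4 of 19 interferon gamma and MHC class I genes were higher in WT, and 1 of 10 milk protein genes, Wap, and 3 of 11 fat globule genes were lower. Wap was at 3541 ± 2053 CPM in WT and 10860 ± 2566 in Raggc IELp (log2 -1.62, SE 0.232). H2-K1 was at 1069 ± 36.6 and 685 ± 115 CPM (log2 0.64, SE 0.0835). Among 7387 genes 32 were higher and 26 lower in WT.

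Of 19 interferon gamma and MHC class I genes 4 were higher (4 adjusted over the list alone), H2-K1, B2m at 0.62, H2-D1 at 0.51 and H2-Q7 at 1.02. For this list alone among the 9 called by camera the call held, at adjusted p = 0.0327 with an estimated correlation. Of 11 fat globule genes 3 were lower (5 adjusted over the list alone; adjusted p = 0.426 with an estimated correlation), Abcg2 at -0.94, Fabp3 at -0.64 and Rab18 at -0.49. Of 10 milk protein genes Wap was lower (1 higher and 5 lower adjusted over the list alone; adjusted p = 0.757 with an estimated correlation), and Csn2 had a value of -0.26 (adjusted p = 0.245). Elf5 was lower at -0.38. Of 18 unfolded protein response genes 2 were lower (8 adjusted over the list alone; adjusted p = 0.303 with an estimated correlation), Manf at -0.56 and Hsp90b1 at -0.36. Of 19 immediate early and heat shock genes 1 was higher and 1 lower, Nr4a1 at 0.80 and Btg2 at -0.75. The metal-binding proteins Mt1 and Mt2 were lower at -0.71 and -0.98, as were Gpx3, a glutathione peroxidase, at -2.19, Fhad1 at -2.02, Cd59a at -2.02 and Def8 at -3.03. Gm43305 at 3.45, Cep85 at 2.24, Gm47283 at 2.47, the peptide hormone gene Cck at 1.66 and the phosphatase inhibitor Ppp1r2 at 0.68 were higher. Endothelial markers summed to 7.60 ± 1.75 CPM in WT and 4.46 ± 1.89 in Raggc IELp, pericyte markers to 19.04 ± 3.67 and 12.4 ± 2.53, and erythroid markers to 9.35 ± 13.5 and 159.8 ± 335. In the largest alveolar cluster alone 25 genes passed, and Wap (-0.97), B2m (0.41), H2-D1 (0.41) and H2-Q7 (0.79) did not. The count was 11 of 1768 genes tested in thinned cells and 22 under the strict hashtag rule.

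In basal cells of WT (n = 5) against Raggc IELp (n = 4), 10 of 13 contractile and 4 of 13 basal identity genes were lower in WT. The smooth muscle actin gene Acta2 (chromosome 19, 34240336 to 34255585) was at 35310 ± 6161 CPM in WT and 50490 ± 3949 in Raggc IELp (log2 -0.52, SE 0.0865). Among 6713 genes 48 were higher and 139 lower in WT. All 13 contractile genes had values below 0, and 10 were lower (12 adjusted over the list alone; fry 0.0357; adjusted p = 0.322 with an estimated correlation), with Tagln at -0.63, Actg2 at -0.66 and Cnn1 at -0.52. Among 13 basal identity genes 4 were lower, the keratins Krt5 at -0.52, Krt14 at -0.54 and Krt17 at -1.21 and the filament gene Vim at -0.96. Krt8 and Krt19, keratins of luminal cells, were lower at -0.83 and -1.64, and the caveola genes Cav1 and Cavin3 at -0.87 and -1.37. Myadm at -1.36, Sparc at -0.54, Cd59a at -2.06, Def8 at -4.41 and the interferon-induced Ifi27l2a at -1.80 were also lower.

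Of 11 cholesterol synthesis genes 2 were lower in these basal cells (5 adjusted over the list alone; adjusted p = 0.322 with an estimated correlation), Hmgcs1 at -1.03 and Fdps at -1.13. Of 19 immediate early and heat shock genes 3 were lower (1 higher and 7 lower adjusted over the list alone; adjusted p = 0.584 with an estimated correlation), the stress factor Atf3 at -1.30, the small heat shock protein Hspb1 at -0.64 and Btg2 at -0.73. Of 17 unfolded protein response genes 3 were lower (1 higher and 5 lower adjusted over the list alone; adjusted p = 0.323 with an estimated correlation), Atf3, Manf at -0.63 and Asns at -1.10. Csn2 was lower at -0.86 (adjusted p = 0.0488), with 6805 ± 862 CPM in WT and 24770, 13820, 5350 and 5841 in Raggc IELp 1, 3, 4 and 5; the call was lost in 9 alternatives, DESeq2 among them, and without Raggc IELp 1 (log2 -0.28), Raggc IELp 3 or any single WT sample. Genes higher in WT were Igfbp5 at 0.91, Errfi1, an inhibitor of EGF receptor signalling, at 1.06, the collagen Col16a1 at 2.04, Opcml at 2.02, Pttg1, securin, at 1.92, Auts2 at 0.77, Gm47283 at 3.17 and the chemokine Ccl2 at 1.19. Hpcal4 was at 27.0 ± 9.40 CPM in WT and had 0 counts in Raggc IELp, as it did in Raggc 1 and Raggc 4. In these cells fibroblast markers summed to 1136 ± 141 CPM in WT and 911 ± 88.8 in Raggc IELp, endothelial markers to 10.3 ± 7.33 and 5.05 ± 4.43, and erythroid markers to 174 ± 378 (850.0 in WT 3) and 3.77 ± 7.54. The count was 63 of 3098 genes tested in cells thinned to 2000 UMIs and 120 under the strict hashtag rule.

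**Figure D4:**
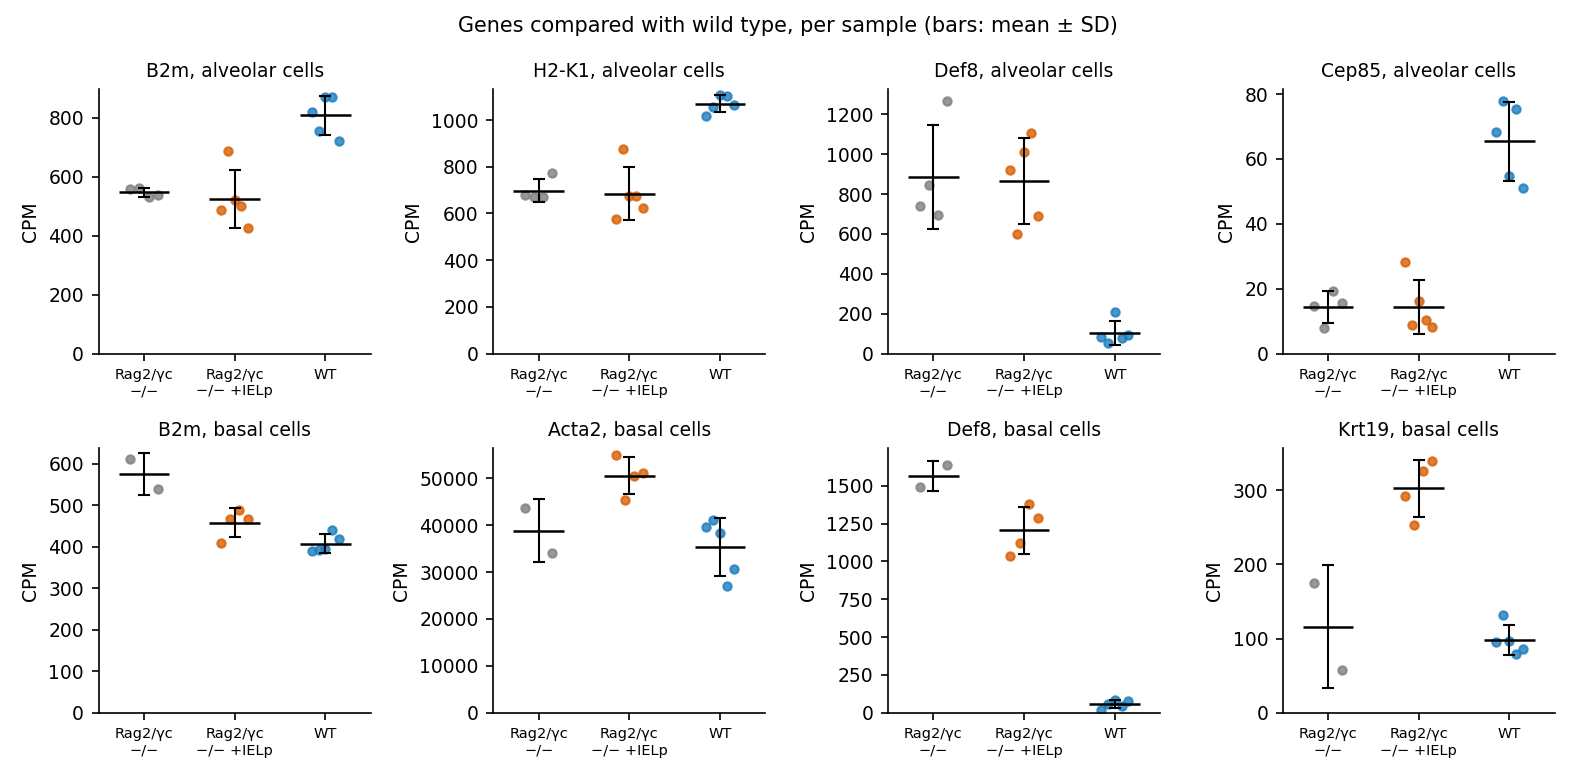
CPM of 4 genes in alveolar cells and 4 in basal cells of each sample (points), by group, with the mean and SD. In alveolar cells B2m was at 547, 525 and 808 CPM in Raggc, Raggc IELp and WT, and Def8 at 887, 866 and 104.

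The genes changed with transfer and those differing between WT and Raggc overlapped in alveolar cells. Both comparisons had 68 genes higher, 8 lower and 1 opposite, against 2.48 and 0.238 expected from the 2 counts alone. Both use the same Raggc samples, which makes them alike by itself. The log2 changes had a covariance over genes of 0.0793, where 40 simulations of unchanged groups gave 0.0338 on average. With the Raggc samples split between the comparisons, in 6 ways, 15 to 26 genes were higher in both (0.523 expected on average) and the covariance was 0.0507 (0.0336 to 0.0662). Over all epithelial cells 8 genes were higher in both (0.835 expected), with a covariance of 0.139 against 0.0402 simulated; with split samples, on average 1 gene was higher in both.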

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

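The tests of explanations and the splits of samples in this part were chosen after the results were seen.

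With transfer, 9 milk protein genes and 10 fat globule genes rose in alveolar cells, with a median log2 change of 0.95. Per the protocol text all samples were pooled in 1 lane, so free milk RNA in the droplets would reach cells of all groups alike. In basal cells these 19 genes were at 197 ± 185 UMIs per cell in Raggc and 164 ± 135 in Raggc IELp, over all samples. Raggc 2, Raggc 3 and Raggc IELp 2 held fewer than 20 basal cells. The others were at 128 and 57.8 in Raggc 1 and Raggc 4. In Raggc IELp 1, 3, 4 and 5 they were at 384, 201, 78.85 and 86.3. The basal level was thus uneven within a group. In the samples with at least 20 basal cells, Csn2 in CPM had a log2 value of 1.16 with transfer (edgeR adjusted p = 0.391). The test set the highest basal level against the alveolar rise. That level was 469 UMIs per cell, in Raggc 2 with only 10 basal cells. Alveolar cells rose by 1412 UMIs per cell (from 2633 ± 975 to 4045 ± 722). A first form of this test, the alveolar minus basal level, gave an exact permutation p of 0.0556 (n = 5 and 4), missed its stated bound and was then replaced by the one above. The background of the Raggc 1 and Raggc 2 hashtags is argued against as the whole cause, since 13 of the 19 genes stayed higher without these samples (median 1.08). A shift of cells among alveolar clusters stays open and is a candidate explanation for the milk protein genes. In the largest cluster alone the median of the 9 fell from 0.98 to 0.25 and 1 of 9 still passed. Over both lists 4 of 19 passed there (0.31), a value seen before the test was set up and limited to milk protein genes. The fat globule list was not left out of the clustering, and Fabp3, which rose with transfer, marks an alveolar cluster. Keeping 1 cluster may thus hold cells near 1 level of the milk genes, so the fall does not decide. A change within cells by transfer was not separated from a shift among clusters.

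Between wild type and both deficient groups 31 genes differed the same way in alveolar cells, 24 higher and 7 lower, among them Def8, Gm43305, Cep85, Cd59a and the MHC class I genes. Def8 was also lower in basal cells of WT (log2 -4.77 against Raggc and -4.41 against Raggc IELp), while B2m and H2-K1 did not pass there. Chromosome segments of another strain could give such differences near the disrupted genes. Of the 29 genes with a position, 6 pairs lay within 10 Mb of each other, against a median of 4 in 10000 random sets, and a share of 0.228 of the random sets had as many. Pairs among the MHC class I genes H2-K1, H2-D1 and H2-Q7, neighbours on chromosome 17, are part of this count with or without such a segment. Cd59a (chromosome 2, 104095753 to 104115410) lay within 10 Mb of Rag2 and 0 genes near Il2rg. Segments of another strain and an effect of the deficiency itself cannot be told apart here. The labels give a single strain for the pool and none per group, and strain would go with the group.

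Basal cells took a larger share in WT (49.8%) than in Raggc (19.8%). Cells left out as hashtag doublets are argued against, since the ratio rule, which takes in 1699 of them, gave a difference of 27.2 percentage points (SE 4.09) and kept the call. Cells assigned on a weak hashtag lead cannot be told apart from a change of the gland: under the strict rule the difference was 23.4 points (SE 10.98) and lost its call, with 8 of only 15 epithelial cells of Raggc 2 basal. Whether non-epithelial cells passing the sort in Raggc play a part stays undecided. Without Raggc 1 and Raggc 2, which held the most, the difference was 33.7 points (SE 4.59, with 2 Raggc samples left). Those samples also had the highest basal shares of Raggc (21.9% and 25.0%, against 17.7% and 14.5%). Leaving them out therefore had to widen the difference, so the test cannot decide. A first bound on its p was replaced because 2 samples can never meet it. Basal and non-epithelial shares correlated at 0.94 in Raggc (n = 4), -0.44 in Raggc IELp (n = 5) and -0.60 in WT (n = 5). A difference in how basal cells of each genotype come through tissue digestion and the sort may also lie behind the difference in basal share and was not tested. A change of the gland by the deficiency was not tested either.

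The number of genes called was compared with 100 of the 126 splits of the same samples in each comparison. No other split tried gave as many genes for alveolar transfer (129 genes, highest other split 46, 1 split as large, the real one) or alveolar WT against Raggc (251, 134 and 1). The same held for alveolar WT against Raggc IELp (58, 20 and 1) and basal WT against Raggc IELp (187, 49 and 1). This argues against chance for these counts, under a bound set after the results were seen. For transfer over all epithelial cells 2 splits gave 13 genes or more. The other split, all Raggc samples with Raggc IELp 2, gave 225 and points to a structure of the samples. The count of 13 therefore does not set the real grouping apart, and chance is not excluded for it. Chance is not excluded for the number of lists called: all cells with transfer (9, highest other 12; 24 splits as large), alveolar transfer (8 and 11; 11), alveolar WT against Raggc (8 and 11; 19), alveolar WT against Raggc IELp (9 and 12; 7) and basal WT against Raggc IELp (7 and 8; 6).

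Some samples lay far from the others of their group: 14 of 126 groups of values tested held such a sample, where chance gives about 1 in 20. Raggc IELp 4 held 227 assigned cells (others 106 to 137), and the WT 1 hashtag stood 6.50 times above its background (others 13.5 to 14.8). In alveolar cells, Elf5 was at 658 CPM in Raggc 4 (others 737 to 752), Krt8 at 663 in Raggc IELp 4 (547 to 581) and Lalba at 229.8 in Raggc 1 (90.7 to 110.1). In basal cells Krt8 was at 1094 CPM in Raggc IELp 1 (651 to 719). Summed markers of other cell types in alveolar cells stood apart for adipocytes in Raggc IELp 1 (84.0 CPM; 32.7 to 43.9), endothelial cells in WT 1 (4.53; 7.89 to 8.75), fibroblasts in Raggc IELp 5 (29.7; 8.55 to 11.9) and myeloid cells in Raggc 2 (99.7; 31.8 to 43.0). Erythroid markers did so in alveolar cells of Raggc IELp 5 (759; 0 to 34.9) and WT 5 (33.4; 2.63 to 3.65), and in basal cells of Raggc IELp 5 (15.1; 0 in the others) and WT 3 (850.0; 0 to 11.1).

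The effect of the group differed between basal and alveolar cells for some genes, in a fit with a class by group term (8885 genes; n = 2, 4 and 5); those named here outside the naming rule were chosen after their values were seen. With transfer 4 genes differed: Igfbp5 (basal minus alveolar log2 change -1.21), Cald1 (1.67), Krt19 (1.47) and Ccn2, which was too low in alveolar cells to pass the low-count filter there, so that its value is not read as a difference between the classes. Cald1 rests on a low alveolar level, 14.0 CPM with transfer and 31.8 without (log2 -1.15, edgeR adjusted p = 0.0752). In basal cells of Raggc 1 and Raggc 4 it was at 2713 and 2617 CPM, with a log2 change of 0.26. Its value is therefore not read as a clear difference between the classes either. For WT against Raggc 5 differed: Def8 (-1.48), H2-K1 (-1.01), B2m (-0.98), Cbr2 (-1.25) and Ucp2 (-1.05). For WT against Raggc IELp 30 differed, 6 higher and 24 lower in basal cells, among them Krt19 (-1.87), B2m (-0.91), H2-K1 (-0.79), H2-D1 (-0.74), Tagln (-0.91) and Anxa1 (-1.30); haemoglobin genes among the 6 rest on the single samples with erythroid markers. In simulated data for WT against Raggc IELp this fit recovered 65.5% of genes changed 4-fold; the other 2 comparisons, with 2 basal Raggc samples, were not simulated.

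The 445 assigned cells outside the epithelium were not part of the comparisons; they were found although the sort was meant to remove blood and vessel cells.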

How the results depend on the processing

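The strict hashtag rule, the thinned gene comparisons, the largest alveolar cluster alone, the alveolar cells without clusters of few genes, the minimum of 10 cells and the set without Raggc 1 and Raggc 2 (each also for gene lists except thinning, and the first and last for shares), and for gene lists the ratio rule and the replicate block, were chosen after seeing the data; the other alternatives were chosen before the data were examined. Over all alternatives, counts of genes stayed within 1.5 times in 90 of 154 cases and counts of lists in 91 of 111. Named genes kept their direction and side of the threshold in 9383 of 10155 cases (1 reversed, 534 no longer passed, 237 newly passed), gene lists in 2663 of 2894 (5 reversed, 138 lost, 88 gained) and class shares in 173 of 216 (38 lost, 5 gained). Kept cases include results that passed neither before nor after, so these totals do not show how often calls held. All 38 lost cases of shares fell on the basal, alveolar and progenitor shares of WT against Raggc, the only share results called. For shares, direction was checked only where the main result was called. The cause was not tested for any change below unless one is named. Thinned cells left fewer genes to test (3905 over all cells, 1768 alveolar and 3098 basal, against 9282, 7387 and 6713), so their counts below are not losses alone. Of the 32 named genes that passed in alveolar cells with transfer, 30 of 30 given still passed with DESeq2, 20 without Raggc 1 and Raggc 2, 17 of 30 in thinned cells and 10 in the largest cluster alone.

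For transfer over all epithelial cells (13 genes) the count was 119 with DESeq2, 24 with upper-quartile normalization, 411 with no low-count filter, 74 with the ratio rule, 24 with Scrublet calls removed, 1 with the strict rule, 58 in thinned cells and 0 without Raggc 1 and Raggc 2 (edgeR, 1060 at an unadjusted p under 0.05). For alveolar transfer (129) it was 218 with no filter, 272 with the ratio rule, 67 with the 20% mitochondrial limit, 56 with the strict rule, 80 with at least 50 cells, 59 without Raggc 1 and Raggc 2, 34 in the largest cluster alone and 32 in thinned cells. For alveolar WT against Raggc (251) it was 408 with no filter, 79 with the 20% limit, 79 with the strict rule, 103 without Raggc 1 and Raggc 2 and 28 in thinned cells. For alveolar WT against Raggc IELp (58) it was 126 with no filter, 38 with the 20% limit, 22 with the strict rule, 25 in the largest cluster and 11 in thinned cells. For basal transfer (2) it was 28 with no filter, 1 with the replicate block, 1 with only the groups compared, 5 with Scrublet calls removed, 5 with at least 10 cells and 1 in thinned cells. For basal WT against Raggc (5) it was 1 with upper-quartile normalization, 13 without milk protein genes, 36 with no filter, 1 with the block, 12 with only the groups compared, 20 with the ratio rule, 15 with at least 10 cells and 3 in thinned cells. For basal WT against Raggc IELp (187) it was 123 with DESeq2, 120 with the strict rule and 63 in thinned cells.

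The estimated correlation took the number of lists called from 9 to 0 (all cells, transfer), 8 to 0 (alveolar transfer), 8 to 0 (alveolar WT against Raggc), 9 to 1 (alveolar WT against Raggc IELp), 3 to 0 (basal transfer) and 7 to 0 (basal WT against Raggc IELp). Thinned cells gave 5 lists for alveolar transfer, 5 for alveolar WT against Raggc IELp, 0 for basal transfer and 3 for basal WT against Raggc IELp, and the largest cluster alone gave 3 for alveolar WT against Raggc IELp. The ratio rule gave 8 lists for basal transfer and 6 for basal WT against Raggc (0 before), and at least 10 cells gave 7, 2 and 4 for the 3 basal comparisons. In the largest cluster alone Gm26917 turned to 0.73 with transfer, and camera's direction turned for fatty acid and triglyceride synthesis with transfer (adjusted p = 0.0960) and in WT against Raggc IELp (0.294), as for milk proteins in the latter (0.0910). With the ratio rule it turned for ribosomal proteins in basal cells with transfer (adjusted p = 0.830) and in WT against Raggc IELp (0.932).

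The difference in alveolar share between WT and Raggc IELp newly passed at resolution 1.0 (-18.6 points) and with the 20% limit (-16.5), and the hormone-sensing share with transfer with the ratio rule (1.95). The progenitor share of WT against Raggc lost its call at resolution 1.0 (-9.84), with the left-out lists kept in clustering (-12.3), the 20% limit (-11.2), Scrublet calls removed (-5.07), the strict rule (-6.41), on the logit scale (-1.19) and without Raggc 1 and Raggc 2 (-5.00). The basal and alveolar shares of WT against Raggc lost theirs with the strict rule (23.4 and -19.3) and without Raggc 1 and Raggc 2 (33.7 and -29.7), where fewer arrangements can be drawn.

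Leaving out each sample gave 3 to 243 genes for transfer over all cells (3 without Raggc 2, 4 without Raggc 3, 20 without Raggc 4, 20 without Raggc IELp 5, 243 without Raggc IELp 2), and 76 to 128 for alveolar transfer (80 without Raggc 2, 76 without Raggc 3, 85 without Raggc IELp 2). It gave 1 to 16 for basal transfer (16 without Raggc 1, 4 without Raggc IELp 1, 1 without Raggc IELp 5) and 128 to 285 for alveolar WT against Raggc (149 without Raggc 2, 128 without Raggc 3). For alveolar WT against Raggc IELp the range was 29 to 74 (32 without Raggc IELp 1, 29 without Raggc IELp 2, 37 without WT 4), and for basal WT against Raggc IELp 115 to 181 (115 without Raggc IELp 4). For basal WT against Raggc it was 1 to 27 (1 without Raggc 1, 27 without Raggc 4, 2 without WT 1, 1 without WT 3); without Raggc 1 or Raggc 4 the lone Raggc sample is assumed to vary like the other groups. List counts ranged from 1 to 4 for basal transfer (1 without Raggc 4), 3 to 9 for basal WT against Raggc IELp (3 without WT 4) and 0 to 1 for basal WT against Raggc (1 without Raggc 4 or WT 5). Shares of WT against Raggc ranged from 26.2 to 32.1 points for basal, -28.3 to -23.5 for alveolar and -5.74 to -4.34 for progenitor cells, and all lost their call because fewer arrangements can be drawn. For WT against Raggc IELp the basal difference ranged from 14.8 to 23.6 and the alveolar one from -21.9 to -14.1, both newly passing without Raggc IELp 5.

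Without milk protein genes all 10 called fat globule genes still passed with transfer in alveolar cells (median 0.83 against 0.84); this had been set up as a test of a few genes taking most counts as an explanation of the pattern, and was dropped from those tests after its value was seen, which met the bound set against that explanation. Samples of the same number were not alike: the median correlation over genes in alveolar cells was 0.00175 for 13 such pairs, and with the number as a block 120, 221 and 54 genes passed in the 3 alveolar comparisons and 193 in basal WT against Raggc IELp. Not run were the 5% mitochondrial limit and the strict rule for the basal comparisons with Raggc, and at least 50 cells for basal transfer, since too few Raggc samples were left. Fits per hashtag without groups were not needed. The basal comparisons with Raggc, which 2 Raggc samples entered, recovered the fewest simulated 2-fold changes (28.4% and 14.9%); depth and number of samples were not separated.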

Other observations

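The shares of alveolar clusters were tested after the data were seen; the gene list tests were chosen before, and the test without the cycling cluster after the lower proliferation genes were seen but before its own result was.

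Cells that were not epithelial differed in kind between the groups, as values with no test. Macrophages were 12.2% ± 8.28 (SD, n = 4) of assigned cells in Raggc, 3.25% ± 1.43 (n = 5) in Raggc IELp and 1.85% ± 0.890 (n = 5) in WT. Fibroblasts were 12.9% ± 2.64, 12.5% ± 5.87 and 4.95% ± 1.84, and endothelial cells 8.35% ± 8.38, 0.336% ± 0.752 and 0.404% ± 0.0644. In Raggc 1 to 4 macrophages were 18.8%, 19.8%, 4.12% and 5.91% and endothelial cells 9.38%, 19.8%, 2.06% and 2.15%, so the high values lie in the 2 samples with the highest hashtag background; the Raggc means were 5.02% and 2.11% without both, and 4.53% for endothelial cells without Raggc 2 alone. Mast cells were 1.17% ± 0.922, 0.862% ± 1.01 and 0.618% ± 0.520. Adipocytes, pericytes and Schwann cells numbered 10, 5 and 5 in all.

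Alveolar cells formed 5 clusters, and no difference in their shares between groups passed at an adjusted p of 0.05 over 15 exact permutation tests. A cluster high in Lao1, Fabp3, Olah and Spp1, with a median of 18131 UMIs per cell, was 24.0% ± 8.22 of alveolar cells in Raggc IELp (n = 5), 22.8% ± 8.29 in WT (n = 5) and 7.78% ± 4.56 in Raggc (n = 4), with exact adjusted p of 0.0714 and 0.0595 against Raggc. A cluster high in Gm26917 and Camk1d was 4.10% ± 2.04, 5.73% ± 1.75 and 15.6% ± 6.995 in the same order (exact adjusted p = 0.0595 for each group against Raggc). Both of these tests had the smallest exact permutation p possible, 0.00794. They could not pass over 15 tests unless another test also reached that bound. A cluster of few genes per cell, high in Wap, was 25.4% ± 5.15, 13.6% ± 3.76 and 13.7% ± 10.5. The largest cluster was 41.4% ± 6.24, 54.5% ± 8.79 and 55.6% ± 9.56, and the cycling cluster 5.11% ± 1.95, 3.43% ± 2.41 and 7.38% ± 4.12.

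Some lists moved in camera with 0 single genes past the test over all genes in edgeR. In alveolar cells of WT against Raggc IELp, all 6 type I interferon genes lay below 0 with a median log2 change of -0.35 (3 lower adjusted over the list alone; adjusted p = 0.343 with an estimated correlation). In the same comparison 14 of 15 cholesterol synthesis genes lay below 0 (median -0.49; 2 lower adjusted over the list alone; adjusted p = 0.273 with an estimated correlation), and 11 of 13 mitochondrially encoded genes above 0 (median 0.15; adjusted p = 0.644 with an estimated correlation). The direction of the next 2 results turned under the ratio hashtag rule (camera adjusted p = 0.830 and 0.932). In basal cells 80 of 83 ribosomal protein genes lay below 0 with transfer (median -0.17; adjusted p = 0.787 with an estimated correlation), and 74 of 83 above 0 in WT against Raggc IELp (median 0.10; adjusted p = 0.699 with an estimated correlation).

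One hypothesis was that fewer cells of the cycling alveolar cluster account for the lower proliferation genes in alveolar cells with transfer (median log2 change -0.87 over 24 genes). Without that cluster the median was -0.86 over the 15 genes still tested, with 15 below 0, against -0.75 over the same genes with all cells. Fewer cells of that cluster were thus not the whole source. The proliferation list took no part in the clustering, so cycling cells may also lie in other alveolar clusters. The test therefore does not speak to the number of cycling cells as a whole.

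Markers of lymphocytes other than Cd3e went different ways. Cd3d, Cd3g and Nkg7 had 0 UMIs in both deficient groups, and 3, 5 and 18 UMIs in WT. They were seen in 0.158%, 0.0791% and 0.237% of WT cells. A count of 0 allows more than that in Raggc (0.482%) and Raggc IELp (0.429%), so it shows no difference from WT. Jchain had 492 UMIs in 1 WT cell and 1 UMI in Raggc IELp. The B cell genes Ighm and Cd79b were seen most often in Raggc: Ighm in 5.94% of cells (63 UMIs, 44 of them in Raggc 1 and 0 in epithelial cells), against 2.00% in Raggc IELp and 1.11% in WT, and Cd79b in 1.12%, 0.286% and 0.396%. In Raggc 1 to 4, Ighm was seen in 23, 7, 2 and 5 of 224, 116, 97 and 186 cells. Cd79b was seen in 2, 5, 0 and 0 of them. The high Raggc values thus lie in Raggc 1 and Raggc 2, the samples with the highest hashtag background. These values were not tested.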
